A study of Mus musculus with 4 samples.

How the data were processed

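Poly(A) RNA was sequenced from 4 samples of mouse spleen enlarged by lymphoma. Per the labels' protocols, spleen cells were depleted of red cells by ACK lysis, washed and passed through a strainer before RNA extraction, and the libraries were made from fragmented poly(A) RNA with random hexamer priming. No sort for tumour cells is described, so each library holds tumour cells and whatever other spleen cells remained. All 4 samples carry the same tissue, cell type, genotype and treatment labels. They were therefore treated as 1 group of 4 libraries, called lymphoma 1 (titled GW19), lymphoma 2 (GW95), lymphoma 3 (GW255) and lymphoma 4 (GW328), numbered in accession order. The labels do not say which transgene was carried. No second group is labelled, so no test between conditions exists, and comparisons here are between single libraries. Differences between them are stated by fixed rules of size, and intervals cover counting error only.

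The authors deposited gene counts as whole numbers, made with STAR 2.4.2a against mm10 per the submitters' processing notes. The annotation release, strand setting and filters are not given in the sources used here. The authors deposited a further table whose values were read as FPKM, made with Cufflinks 2.2.1 per the submitters' processing notes. That table names no unit. Its values are not whole numbers and behave as values per kilobase. It also holds 5 columns that match no sample label, and these were not used. The count table has 24969 rows with symbols in capitals. Of these, 24802 matched a mouse symbol in the reference annotation regardless of case and are printed in the mouse form. In 26 rows the gene name had been turned into a date, as spreadsheet programs do. These rows held between 0.191% and 0.201% of counts per library and were left out of library sizes and all results, leaving 24943 genes. Both tables contained 0 rows for immunoglobulin or T cell receptor V, D, J or constant segments under their standard symbols. The planned shares of receptor V segments therefore have no values.

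Total counts were 9441857, 9334572, 9602413 and 7773546 for lymphomas 1 to 4. A count of 0 allows up to 3 counts, which is 0.379, 0.335, 0.294 and 0.330 CPM (counts per library scaled to a common total). CPM were computed with effective library sizes from edgeR 4.0.16 TMM factors (0.838, 0.961, 1.06 and 1.17), in R 4.3.3. TMM factors and dispersion were estimated on the 13543 genes with 1 CPM or more in at least 1 library. Filters on CPM used values before TMM scaling. The spread between tumours was summarised by the biological coefficient of variation from edgeR's estimateDisp with an intercept-only design. A gene had a large spread if its highest and lowest library differed 8-fold or more in CPM + 1. A gene stood apart in a library if that library lay 8-fold or more above or below the nearest of the other libraries, with at least 10 CPM in the high library or libraries. The pseudocount of 1 CPM understates the change of genes near the floor.

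The rules below were fixed before the data were examined. They comprised 37 gene lists (lineages, other cell types, chromatin complexes, p63 and p53 targets, signalling programmes, housekeeping and sex-linked genes), for each of which the median log2(CPM + 1) of the measured members was taken per library. The median SD over libraries of the members that passed the filter was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. That percentile describes these libraries and is not a p-value. The genes named are the fusion partner and p53 family genes, the member of each list with the highest mean and the one with the largest SD, the 3 genes farthest above and 2 farthest below in each library among those standing apart, leaving out receptor segments, pseudogenes and provisional gene names, and the 5 genes with the highest mean. A gene that the rule names is not reported here. Genes from outside this rule are marked as chosen after their values were seen.

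The rules were tested on simulated counts for all 24943 genes, drawn with a gene-wise CV of 20%. Of 50 genes raised 16-fold in 1 library, 98% were called, and of 50 lowered 16-fold, 84% were called. Genes changed 4-fold lie below the 8-fold rule and 0 were called. That CV is far below the spread between the libraries themselves (biological coefficient of variation 0.839), so these rates describe the rule's arithmetic and not its error rate here. Of 100 lists of unchanged genes, 4 reached the 95th percentile of spread. The simulated genes varied independently of each other, so this share is not an error rate for lists of genes that vary together.

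Alternatives were DESeq2 1.42.0 size factors, no filter, a filter of mean CPM of 5 or more, a pseudocount of 0.25 CPM, a 4-fold rule, a 5 CPM threshold for detection, the FPKM table, and leaving out each library in turn. Gene positions and exon lengths are from GENCODE M21 (GRCm38, the assembly also called mm10). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.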

Results

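RNA-seq profiles were collected from 4 samples of mouse spleen enlarged by lymphoma, in a series that asks what a TP63 fusion does in mouse lymphomagenesis. TP63 encodes p63, a transcription factor of the p53 family, and TBL1XR1, a subunit of the NCoR corepressor complex, is a partner of TP63 in fusions of human lymphoma. The 4 samples share every label and form 1 group, so the comparisons are between single libraries, with no test between conditions and no p-value. The labels do not say that the samples came from separate animals, and the spread between them may be partly technical. The libraries held between 7773546 and 9602413 counts, and 11628 ± 503 genes (SD, n = 4) reached 1 CPM. The most abundant genes were the translation factors Eef1a1 (23426 ± 10347 CPM, SD, n = 4) and Eef2 (8699 ± 3517 CPM) and the ribosomal protein genes Rpsa (7484 ± 3820 CPM), Rps2 (5597 ± 4074 CPM) and Rplp0 (5568 ± 3010 CPM).

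The mouse Trp63 gene (chromosome 16, 25683763 to 25892102, plus strand, GRCm38, protein coding) was detected at a low level in each library. It held 11, 29, 52 and 34 counts in lymphomas 1 to 4. These are 1.39 CPM (exact Poisson 95% interval 0.694 to 2.49), 3.23 CPM (2.17 to 4.64), 5.10 CPM (3.81 to 6.69) and 3.74 CPM (2.59 to 5.22). The interval of lymphoma 1 lay below those of lymphomas 3 and 4 and overlapped that of lymphoma 2. Over the 4 libraries Trp63 averaged 3.37 ± 1.54 CPM (SD, n = 4). The count is for the mouse gene as annotated, and the labels do not state the transgene's sequence. Reads from a transgene of another species need not be in it. Tbl1xr1 (chromosome 3, 22076652 to 22216594, plus strand, protein coding) was well expressed at 117 ± 36.2 CPM (SD, n = 4), with its highest value of 167 CPM in lymphoma 4. The tumour suppressor gene Trp53 was at 254 ± 104 CPM, between 138 CPM in lymphoma 4 and 380.2 CPM in lymphoma 1. Trp73 had 3 counts in lymphoma 4 (0.330 CPM, interval 0.0680 to 0.964) and 0 in the other libraries. The list of these 4 genes had medians of 4.01, 4.45, 4.49 and 4.68 log2(CPM + 1), with a mean of 4.41, or 6.57 without lymphoma 4, the only library with a count for Trp73. The spread of the 3 genes that passed the filter lay at the 24.8th percentile among random lists of like expression (37.5th without lymphoma 4).

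B cell and T cell genes differed widely between the tumours. The B cell list had a median of 2.36 log2(CPM + 1) in lymphoma 1, 7.10 in lymphoma 2, 7.87 in lymphoma 3 and 9.07 in lymphoma 4 (mean 6.60 ± 2.94, SD, n = 4). Of its 14 genes, 13 were lowest in lymphoma 1, and 10 stood apart below the other 3 libraries there. Cd79a, a signalling chain of the B cell receptor, was at 24.0, 248, 1314 and 1151 CPM in lymphomas 1 to 4. Cd22, a B cell surface inhibitor, had 19 counts in lymphoma 1 and was at 191, 852 and 604 CPM in lymphomas 2 to 4. The pan T cell list was instead highest in lymphoma 1 and lowest in lymphoma 3, with medians of 8.51, 8.21, 2.61 and 6.19, and 13 of its 15 genes were lowest in lymphoma 3. The CD3 chain genes of the T cell receptor complex were near the floor in lymphoma 3. Cd3d was at 653, 480.4, 0.98 and 55.1 CPM, Cd3g at 416, 325, 0.49 and 117 CPM, and Cd3e at 236, 207, 0.59 and 87.7 CPM. Tcf7, a T cell transcription factor, was at 1601, 1241, 23.7 and 157 CPM. Lymphoma 3 thus held B cell genes with almost no CD3 RNA, lymphoma 1 held T cell genes with little B cell RNA, and lymphomas 2 and 4 held both. Both lists lay at the 100th percentile of spread among random lists of like expression, and the pan T cell list at the 94.9th without lymphoma 3. Lymphomas 1 and 2 may not be independent in their values: over the 130 genes largely restricted to lymphoma 1 against lymphomas 3 and 4, Cd3d among them, lymphoma 2 lay at a near-constant 0.690 of lymphoma 1.

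**Figure D1:**
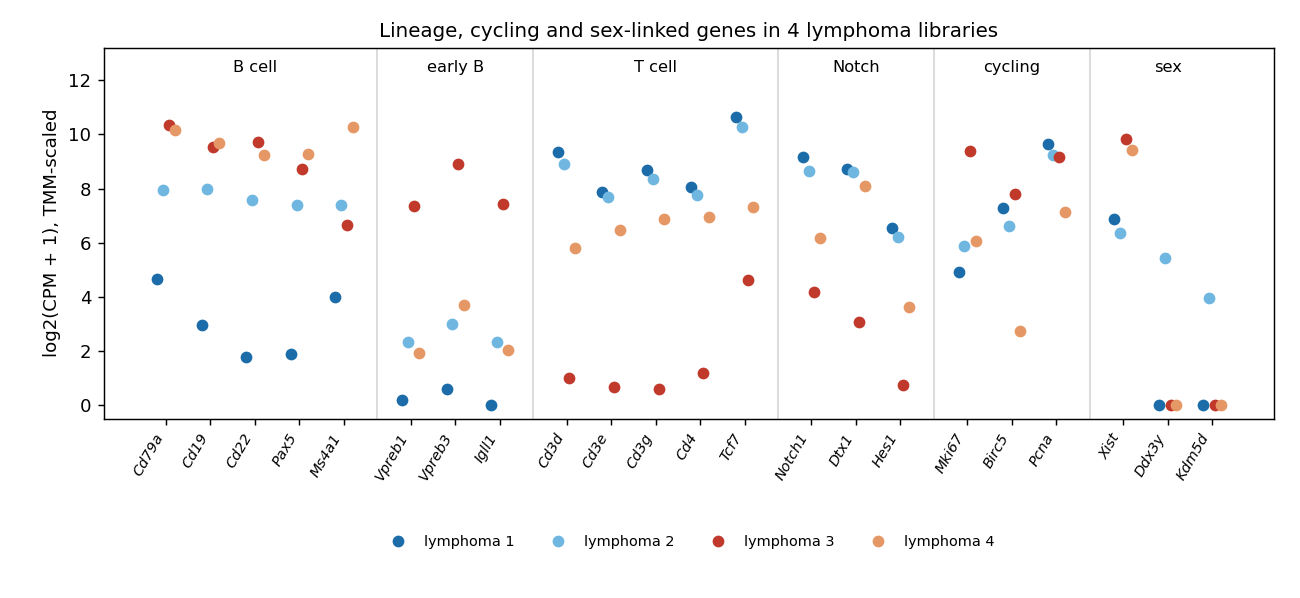
Log2(CPM + 1) of lineage, cycling and sex-linked genes (x axis) in each of the 4 lymphoma libraries (1 point per library and gene, colours give the library). Genes shown beyond those named by rule were picked after their values were seen. Cd3d lies at 653 CPM in lymphoma 1 and 0.98 CPM in lymphoma 3, and Cd79a at 24.0 CPM in lymphoma 1 and 1314 CPM in lymphoma 3.

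Within the B lineage, genes of the surrogate light chain set lymphoma 3 apart. The early B cell list had a median of 5.57 in lymphoma 3 and of 0.17, 2.33 and 1.95 in lymphomas 1, 2 and 4, at the 100th percentile of spread (93.2nd without lymphoma 3). Vpreb3, which is expressed in B cell precursors, was at 483 CPM in lymphoma 3 and at 0.51, 7.03 and 12.0 CPM in lymphomas 1, 2 and 4. Vpreb1 and Igll1, which encode the surrogate light chain and were chosen after their values were seen, were at 164 and 170.3 CPM in lymphoma 3 and at most 4.01 CPM elsewhere. Of the 6 early B cell genes that passed the filter, 4 stood apart above in lymphoma 3, but 2 were lowest there. Those 2 were from among Rag1, Rag2 and Dntt, which are also on the immature T cell and Notch list. The germinal centre list was higher in lymphomas 3 and 4 (medians 3.61 and 3.02) than in lymphomas 1 and 2 (0.70 and 0.93), at the 85.3rd percentile of spread. Bcl6, the germinal centre repressor, was at 0.25, 17.2, 39.9 and 32.3 CPM, whereas S1pr2 lay between 12.4 and 35.1 CPM. Plasma cell genes gave medians of 4.41, 6.02, 5.04 and 4.88 (99.7th percentile, but 63.2nd without lymphoma 1) and did not move together. Jchain, the joining chain of secreted antibodies, was highest at 620 CPM in lymphoma 4 and lowest at 88.4 CPM in lymphoma 3, while the syndecan gene Sdc1 was at 165 and 118 CPM in lymphomas 1 and 2 and at 9.32 and 11.5 CPM in lymphomas 3 and 4.

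Lists of T cell subset genes had their lowest medians in lymphoma 3, but not each of their genes was lowest there. All 5 genes of the CD4 and CD8 list were lowest in lymphoma 3 (medians 6.09, 6.16, 0.26 and 4.10; 99.9th percentile, but 43.9th without lymphoma 3), and Cd4 was at 263, 216, 1.28 and 124 CPM. The list of immature T cell and Notch genes had medians of 6.38, 5.81, 0.62 and 2.53 (100th percentile), and 7 of its 9 filtered genes were highest in lymphoma 1. Dtx1, a Notch target, was at 417, 394, 7.46 and 275 CPM, and Themis, which acts in thymocyte selection, at 90.6, 68.8, 0 and 9.46 CPM. Notch1 itself, chosen after its values were seen, was at 568, 397, 17.2 and 70.6 CPM. Of 9 follicular helper genes, 5 were highest in lymphoma 4, 5 were lowest in lymphoma 1 and 4 were lowest in lymphoma 3 (medians 1.65, 4.17, 0.48 and 5.06; 100th percentile). Among them Cxcr5, which B cells also express, was at 2.15, 49.2, 29.2 and 285 CPM and Sh2d1a at 128, 95.4, 0.20 and 14.7 CPM. Regulatory T cell genes had medians of 4.30, 4.66, 2.14 and 4.86 (96.4th percentile, but 9.01st without lymphoma 3), 3 of 6 being lowest in lymphoma 1 and 3 in lymphoma 3, with Ikzf2 at 46.7, 48.4, 0.39 and 62.9 CPM. Helper subset genes had medians of 0.80, 2.19, 0.20 and 2.04 (97.7th percentile), with Gata3, the Th2 transcription factor, at 94.0, 84.0, 0.49 and 13.9 CPM.

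Most genes of the proliferation list were lowest in lymphoma 4. The proliferation list had medians of 7.27, 6.83, 7.801 and 2.99 (mean 6.22 ± 2.19, SD, n = 4; 100th percentile of spread, but 46.8th without lymphoma 4). Of its 15 genes, 14 were lowest in lymphoma 4, 7 of them standing apart below, and 10 were highest in lymphoma 3. The gene not lowest in lymphoma 4 was Mki67, at 29.6, 58.4, 668 and 66.4 CPM. Shorter transcripts were lower in lymphoma 4 across 10934 genes. The Spearman rho between exonic length and the log2 ratio to lymphoma 4 was -0.325, -0.307 and -0.236 for lymphomas 1, 2 and 3. Whether length accounts for the low proliferation genes was not tested. In lymphoma 4, 9 of 11 neutrophil, 8 of 9 dendritic cell and 7 of 10 NK and cytotoxic genes were at their highest. The survivin gene Birc5 was at 153, 97.9, 222 and 5.61 CPM, and the replication clamp gene Pcna at 809, 597, 577 and 138 CPM. MYC target genes had medians of 7.90, 7.76, 7.81 and 7.05 (58.7th percentile, from 4.10 without lymphoma 4 to 82.6 without lymphoma 1), and 11 of 14 were lowest in lymphoma 4. Ldha, the lactate dehydrogenase gene on that list, was at 3485, 2474, 1530 and 274 CPM. The list of lymphoma oncogenes and suppressors had medians of 5.38, 6.47, 4.95 and 6.96 (90.3rd percentile, 99.4th without lymphoma 4). On it, Ikzf1 was stable at 926 ± 288 CPM (SD, n = 4), whereas the kinase gene Syk was at 5.05, 315, 204 and 1114 CPM. Targets of p53 had medians of 5.48, 5.19, 3.99 and 4.42 (80.6th percentile, 95.2nd without lymphoma 4), with Ccng1 at 243 ± 86.1 CPM and Pmaip1 at 1.14, 9.81, 12.7 and 26.4 CPM.

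The lists of chromatin complexes lay below the 95th percentile of spread with all libraries, a placing that rests on lymphoma 4 for 2 of the 3. Medians of the PRC2 list, the complex that writes H3K27 methylation, were 6.22, 5.99, 6.63 and 6.28 (74.6th percentile), with Rbbp4 at 499 ± 260.4 CPM (SD, n = 4) and Phf1 at 4.17, 50.4, 25.9 and 110 CPM. Its catalytic subunit gene Ezh2, chosen after its values were seen, was at 141, 113, 203 and 26.9 CPM. It was lowest in the library where most proliferation genes were lowest. The NCoR complex list had medians of 5.45, 6.59, 7.03 and 5.82 (79.9th percentile, 97.8th without lymphoma 4 and 34.9th without lymphoma 1), and the corepressor gene Ncor1 was at 42.8, 132, 196 and 262 CPM. The KMT2C and KMT2D list, for enhancer methyltransferase complexes, had medians of 5.48, 6.06, 6.07 and 5.85 (88.8th percentile, 95.25th without lymphoma 4). Kmt2d was at 32.8, 244, 199 and 563 CPM and Kmt2c at 8.59, 86.7, 42.3 and 252 CPM. These transcripts are long, and across 10934 genes longer transcripts were lower in lymphoma 1, with a Spearman rho between exonic length and the log2 ratio of -0.331 against lymphoma 2, -0.201 against lymphoma 3 and -0.325 against lymphoma 4. Longer transcripts were also higher in lymphoma 4, with a rho of -0.307 for the ratio of lymphoma 2 to lymphoma 4 and -0.236 for that of lymphoma 3 to lymphoma 4. Epidermal p63 targets were low, with medians of 1.79, 1.75, 0.53 and 1.30 over 10 of 14 genes with any count (82.8th percentile). The basement membrane receptor gene Itga6 was at 22.8 ± 6.41 CPM (SD, n = 4), and its partner Itgb4 was at 33.7 CPM in lymphoma 3 and at most 0.25 CPM elsewhere.

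Antigen presentation, NF-kB and checkpoint genes were mostly highest in lymphoma 4. All 7 MHC class II genes were lowest in lymphoma 1 and highest in lymphoma 4 (medians 5.44, 8.57, 9.53 and 11.37; 100th percentile). The B cell list had the same order of libraries, and 8 of 9 dendritic cell genes were also highest in lymphoma 4. Cd74, the class II invariant chain gene, was at 90.2, 1150, 1854 and 5942 CPM, and Ciita, its transactivator, at 1.01, 96.5, 63.1 and 286 CPM. MHC class I genes had medians of 7.36, 7.79, 7.75 and 8.47 (60.3rd percentile, 98.8th without lymphoma 4), with B2m at 1291 ± 764 CPM (SD, n = 4). Their transactivator gene Nlrc5 had 0 counts in lymphoma 1 and 56.1, 94.7 and 214 CPM in the others. NF-kB genes had medians of 3.39, 5.15, 3.88 and 6.51 (99.8th percentile, 93.6th without lymphoma 4), and all 9 were highest in lymphoma 4. Nfkbia, the NF-kB inhibitor gene, was at 57.0, 132, 57.5 and 189 CPM and Cd83 at 4.8001, 34.6, 0.98 and 259.8 CPM. Immune checkpoint genes were highest in lymphoma 4 for 6 of 8 (medians 2.90, 3.94, 1.58 and 5.55; 99.8th percentile), with Ctla4 at 1.14, 10.9, 2.36 and 120.0 CPM and Tox at 76.9 ± 32.3 CPM. Interferon response genes had medians of 0.71, 3.12, 1.52 and 2.68 (84.8th percentile, 97.8th without lymphoma 3 and 97.1st without lymphoma 4), with Gbp2 at 1.39, 11.6, 5.20 and 111 CPM. Of the 13 interferon response genes, 8 were highest in lymphoma 2 and 4 in lymphoma 4. JAK-STAT feedback genes had medians of 3.09, 4.07, 3.12 and 3.96 (93.9th percentile, 96.3rd without lymphoma 4), with Pim1 at 15.8, 145, 23.1 and 175 CPM and Socs3 at 7.20, 37.0, 2.06 and 34.7 CPM. Immediate early and stress genes, which respond to tissue handling, were also high in lymphoma 4, and 7 of 9 were highest in lymphoma 2. Their medians were 5.23 and 5.36 in lymphomas 1 and 3 and 8.10 and 7.98 in lymphomas 2 and 4 (99.99th percentile). Fos was at 87.8, 682, 87.3 and 505 CPM, and the heat shock gene Hspa1a at 2.53, 199, 1.28 and 251 CPM.

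Genes of other spleen cells were mostly lowest in lymphoma 1 and highest in lymphoma 4. Highest in lymphoma 4 were 9 of 11 neutrophil, 8 of 9 dendritic cell, 7 of 10 NK and cytotoxic and 9 of 14 macrophage and monocyte genes. NK and cytotoxic genes had medians of 0.25, 4.02, 1.45 and 4.48 (99.98th percentile), and Nkg7 was at 1.01, 23.0, 0.98 and 46.6 CPM. Gzma, which encodes granzyme A, departed from the rest of that list at 1036, 776, 54.3 and 47.1 CPM. Neutrophil genes were lowest in lymphoma 1 for 9 of 11 (medians 1.10, 3.51, 2.61 and 3.61; 95.5th percentile, but 35.1st without lymphoma 4), with S100a9 at 6.44, 40.3, 25.5 and 186 CPM and Ltf at 0.51, 33.9, 9.42 and 74.7 CPM. Macrophage and monocyte genes were lowest there for 10 of 14 (medians 0.59, 2.26, 1.88 and 2.21; 62.8th percentile, 7.04th without lymphoma 1 and 98.03rd without lymphoma 3). Lysozyme gene Lyz2 was at 105, 254, 96.6 and 259.9 CPM, and Cd163 ran against the list at 60.5, 43.0, 1.08 and 0.55 CPM. Dendritic cell genes had medians of 0.17, 1.36, 0.58 and 2.90 (98.9th percentile, 90.6th without lymphoma 1 and 93.4th without lymphoma 4), with Ccr7 at 34.6, 50.4, 3.63 and 46.0 CPM and Siglech at 0.13, 2.68, 2.36 and 40.7 CPM. Stem and progenitor genes had medians of 0, 0.64, 0.26 and 0.82 (97.04th percentile, 88.95th without lymphoma 1). Ly6a, which T cells also express, was at 65.7, 109, 14.4 and 378 CPM (142 ± 162 CPM) and Kit at 0.63, 8.48, 1.08 and 29.5 CPM. The stroma and endothelium list was near the floor in all libraries (medians 0.09, 0.74, 0.14 and 0.99; 45.9th percentile), apart from Pecam1 at 95.9 ± 46.8 CPM and Pdgfrb at 16.2, 11.6, 10.7 and 0.33 CPM. Erythroid (0.59, 1.08, 0.67 and 0.41; 9.88th percentile) and megakaryocyte genes (0.17, 1.0004, 1.79 and 1.14; 40.3rd percentile) were also low, with Car2 at 13.7 ± 12.0 CPM and Gp1ba at 2.58 ± 2.43 CPM (SD, n = 4). The percentiles of these lists were 30.1 and 12.4 without lymphoma 1, and 15.2 and 78.4 without lymphoma 4. Pancreas genes, a check for neighbouring tissue, had medians of 0, 0, 0.26 and 0, and Cela1 was at most 5.05 CPM. The haemoglobin genes were listed at 0 counts in all libraries, although Hbb-b1 had FPKM of 28.4, 170.3, 24.9 and 88.9, so the erythroid list leaves out its most abundant members.

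**Figure D2:**
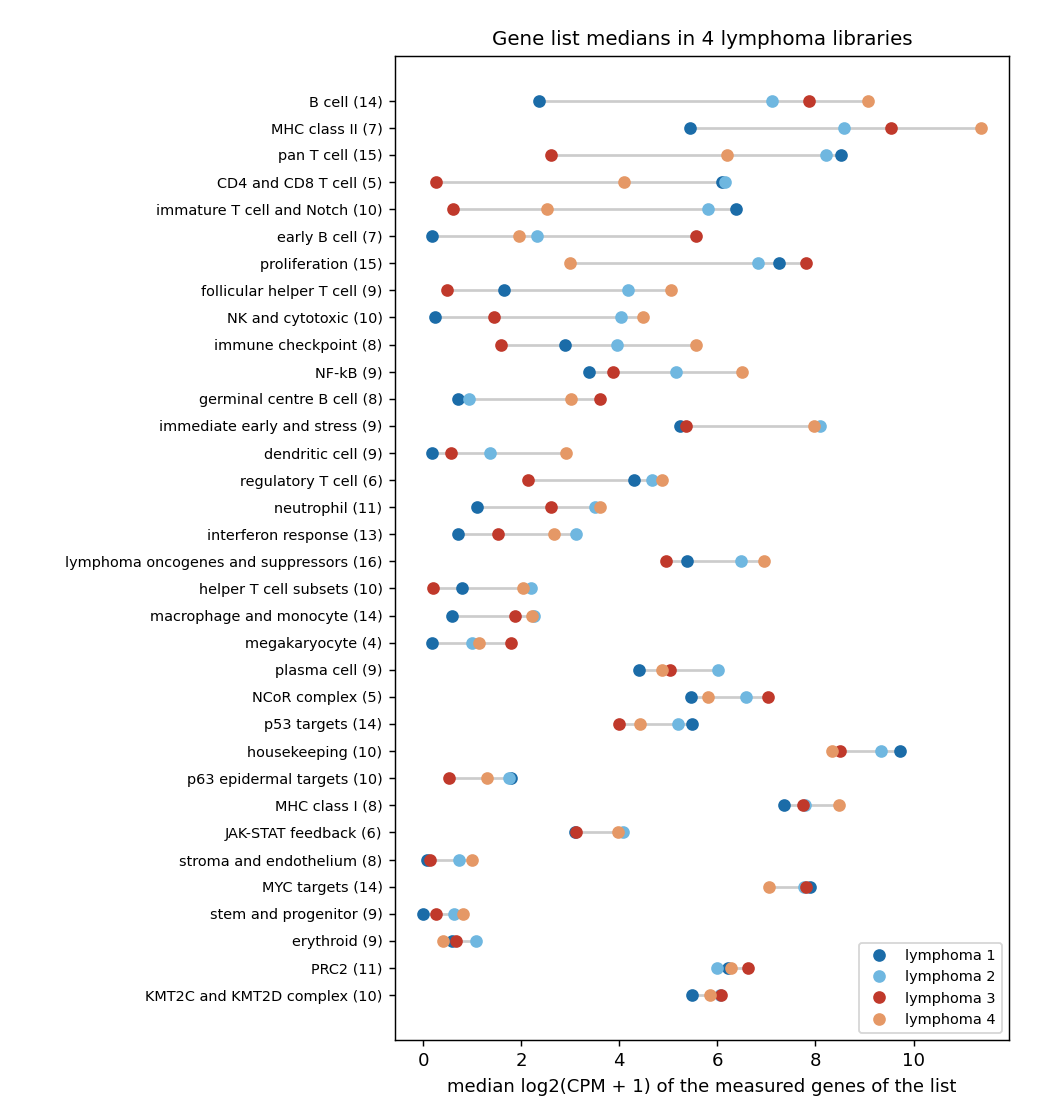
Median log2(CPM + 1) of the measured genes of each list shown (number in brackets) in the 4 lymphoma libraries. Grey lines run from the lowest to the highest library, and lists are ordered by that range. The sex-linked, pancreas, and fusion partner and p53 family lists are not shown. The median of B cell genes ranges from 2.36 in lymphoma 1 to 9.07 in lymphoma 4, and that of KMT2C and KMT2D complex genes from 5.48 to 6.07. A narrow range of medians does not mean stable genes, as Kmt2c varied 29.3-fold and Kmt2d 17.1-fold between libraries.

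Across all genes the tumours were far apart. The biological coefficient of variation was 0.839 over the 4 libraries and 0.964 without lymphoma 2, whose values may not be independent of those of lymphoma 1. Of 13543 genes, 2208 (16.3%) differed 8-fold or more between the highest and the lowest library, and 12 of the 37 lists had library medians that far apart. Without lymphoma 1, 3 or 4 the number of such genes was 1401, 1407 or 1118, and without lymphoma 2 it was 2175. The spread of 19 lists reached the 95th percentile, and that of 16 to 22 lists with 1 library left out. Housekeeping genes had medians of 9.73, 9.35, 8.50 and 8.34 (67.3rd percentile, 30.5th without lymphoma 1), with Gapdh at 4654, 3232, 2052 and 531 CPM and Pgk1 at 1052, 762, 409.7 and 97.97 CPM. A total of 481 genes stood apart in a single library. In lymphoma 3, 111 lay above and 89 below the others, and in lymphoma 4, 110 above and 63 below. In lymphoma 1, 103 lay below and 0 above, and in lymphoma 2, 5 lay above and 0 below. No adjustment for transcript length was made, and longer transcripts were lower in lymphoma 1 relative to each other library. These counts depend on which libraries are compared. Without lymphoma 2, the total was 1093, with 169 above and 232 below in lymphoma 1 and 370 above and 103 below in lymphoma 4. Without lymphoma 1, 112 lay above and 5 below in lymphoma 2, and 165 below in lymphoma 3. Without lymphoma 3, 202 lay below in lymphoma 1 and 203 below in lymphoma 4. Without lymphoma 4, 35 lay above in lymphoma 2 and 310 below in lymphoma 3.

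The genes farthest above in lymphoma 3 were the serine protease gene Prss23 (406 CPM), the myosin light chain gene Myl4 (2096 CPM) and Crhbp, which encodes the corticotropin-releasing hormone binding protein (166 CPM). Prss23 was 923-fold higher than in the next library (exact 95% interval 360.1 to 3388) and Myl4 269-fold higher (212 to 345). Crhbp had 0 counts in the other libraries and was at least 439-fold higher, taking the floor of 3 counts. In lymphoma 4 they were the transcription factor gene Zbtb32 (53.5-fold over the next library, 36.8 to 80.7), the basement membrane gene Nid1 (36.8-fold, 27.6 to 50.1) and the chemokine-scavenging receptor gene Ackr2 (50.2-fold, 29.2 to 94.8). Farthest below in lymphoma 4 were the matrix metalloproteinase gene Mmp14 (269, 175, 204 and 1.32 CPM) and Lmcd1 (97.1, 59.9, 30.4 and 0 CPM). The pairs farthest below were Nlrc5 and Cd22 in lymphoma 1 and Cd3g and Cd3e in lymphoma 3. The intervals cover counting error between single libraries only.

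Lymphomas 1 and 2 were the closest pair. Their Spearman rho across 13543 genes was 0.944 (Pearson r 0.946), against 0.803 for lymphomas 1 and 3, 0.710 for 1 and 4, 0.852 for 2 and 3, 0.849 for 2 and 4 and 0.776 for 3 and 4. Genes are not independent replicates, and no p-value is attached to these values. Their counts differed well beyond sampling noise, with a chi-square of 45.6 per degree of freedom, so they were kept as 2 libraries. The difference ran in 1 direction. In lymphoma 2, 233 genes were 8-fold or more higher than in lymphoma 1, among them 12 of the 14 B cell genes, and 0 genes were that much lower. There were 3355 genes at 50 CPM or more in lymphoma 1 before TMM scaling. In scaled CPM, 1 of them was at under 50% of its lymphoma 1 level in lymphoma 2, against 844 in lymphoma 3 and 1741 in lymphoma 4. For the 130 genes that were 8-fold or more higher in lymphoma 1 than in lymphomas 3 and 4, the ratio of lymphoma 2 to lymphoma 1 had a median of 0.690 and an interquartile range of 0.650 to 0.735.

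**Figure D3:**
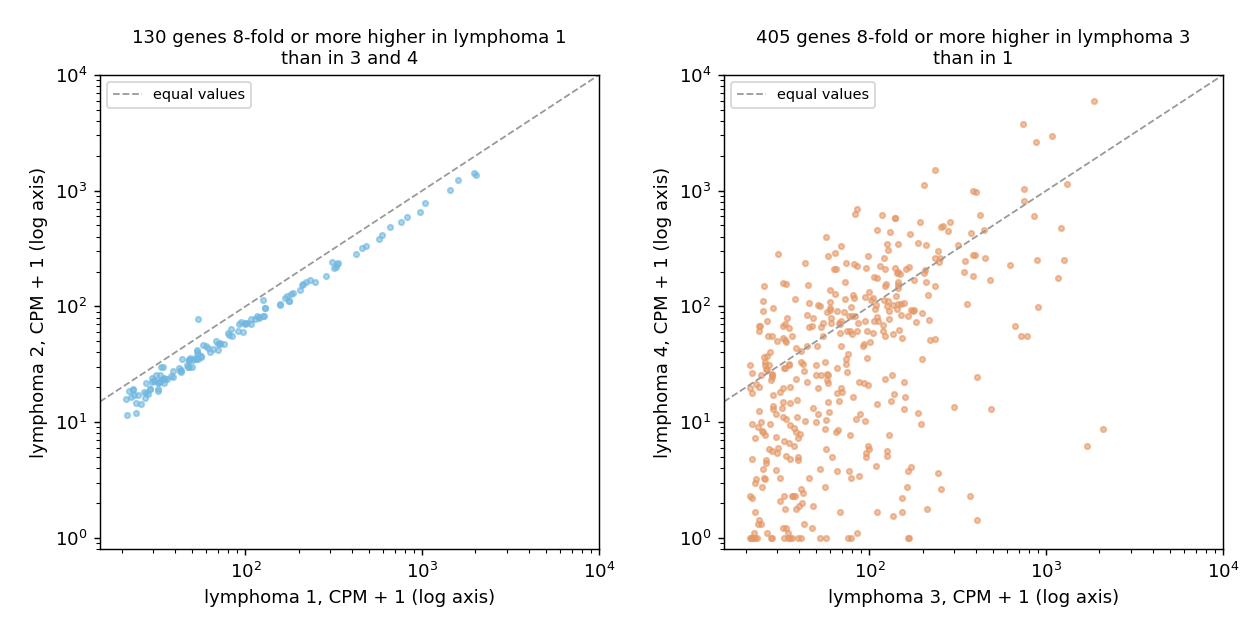
CPM + 1 on log axes for genes at 20 CPM or more. Left, lymphoma 2 (y) against lymphoma 1 (x) for the 130 genes 8-fold or more higher in lymphoma 1 than in lymphomas 3 and 4, which lie on a line parallel to equal values (dashed) at a median ratio of 0.690. Right, for contrast, lymphoma 4 (y) against lymphoma 3 (x) for the 405 genes 8-fold or more higher in lymphoma 3 than in lymphoma 1, whose ratios have an interquartile range of 0.111 to 1.28.

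Sex-linked genes differed between the libraries (99.98th percentile of spread). Y-linked genes were found in lymphoma 2 alone, at 763 counts over 4 genes (85.1 CPM), against 0 counts in each of the other libraries. Ddx3y (chromosome Y, 1260771 to 1286629, minus strand, protein coding) was at 42.3 CPM, Eif2s3y at 20.6 CPM and Kdm5d at 14.4 CPM. For Ddx3y this was at least 112-fold higher than the floor of 3 counts. Xist (chromosome X, 103460366 to 103483254, minus strand, long noncoding), the RNA of the inactive X of female cells, was at 116 CPM in lymphoma 1, 80.2 CPM in lymphoma 2, 901 CPM in lymphoma 3 and 681 CPM in lymphoma 4. Lymphoma 2 therefore held both Xist and Y-linked RNA, and its Xist was 0.693 of that in lymphoma 1.

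The 2 deposited tables ranked genes alike within a library. Spearman rho between CPM and FPKM over 13543 genes was 0.932, 0.906, 0.914 and 0.888 for lymphomas 1 to 4 (mean 0.910 ± 0.018, SD, n = 4). Some genes with high FPKM were listed at 0 counts. By their symbols, several of them are pseudogenes or predicted genes, such as Rpl34-ps1, Oaz1-ps and Gm15772, whose FPKM need not mean abundant RNA of their own. Of 2495 genes with FPKM of 10 or more in all libraries, 22 were listed at 0 counts throughout, including Eno1, the glycolytic enolase gene (FPKM of 619, 510, 369 and 153), Rpl26 (256, 200.3, 202 and 31.7) and Oaz1 (179, 140.2, 171 and 96.6), which were chosen after their values were seen. In the FPKM table Trp63 averaged 0.179 ± 0.169 (SD, n = 4) and Tbl1xr1 6.61.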

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

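A library was called far from the others where its gap to the nearest, divided by the range of all 4, exceeded Dixon's 95% critical value for 4 samples. Levels were taken as log2(CPM + 1). Of 128 results tested, 19 passed. Chance passes about 1 in 20 groups of values, but many of the genes tested had been named because 1 library stood apart or for a large SD, which favours a wide gap. The number that passed is therefore not comparable with that rate. None of the 19 had lymphoma 1 as the distant library, 4 had lymphoma 2, 9 had lymphoma 3 and 6 had lymphoma 4. Because lymphomas 1 and 2 are close in many genes, a gene high or low in both cannot pass. The tests on the pair of lymphomas 1 and 2 below were chosen after the values were seen, and those on Malat1 were fixed before their results.

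In lymphoma 3 the gaps were 0.9583 for Prss23, 0.8751 for Myl4, 1 for Crhbp and 0.9365 for Itgb4, all high. They were 0.842 for Cd4, 0.9238 for Ikzf2, 0.8933 for Dtx1 and 0.8475 for Ccr7, all low. The pancreas list was high there with a gap of 1, at a median of only 0.26 log2(CPM + 1). In lymphoma 4 the gaps were 0.8535 for total counts (low), 0.8362 for the MYC target list (low), 0.85 for Pdgfrb (low), 0.9102 for Mmp14 (low), 0.9129 for the share of counts in Malat1 (high) and 1 for Trp73 (high, on 3 counts). In lymphoma 2 the gaps were 1 for the list of sex-linked genes and 1 each for Ddx3y, Eif2s3y and Kdm5d, all high.

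Lymphoma 2 held Y-linked RNA together with Xist, and the 130 genes restricted to lymphoma 1 against lymphomas 3 and 4 lay in lymphoma 2 at a near-constant ratio. A candidate explanation is that lymphoma 2 holds RNA of the tumour in lymphoma 1 together with RNA of other cells, B cells and male cells among them. Beyond counting error the CV of that ratio, taken from its interquartile range, was 0.0590, against 0.790 to 1.60 for the same measure in 6 other comparisons of libraries, 4 of which restricted genes against 1 library only. The CV from all 130 genes was 0.116, against 1.12 to 4.78. For a second, independently arisen tumour of the same lineage, a value above 0.5 was set, but only after the values were seen. The 0.0590 lay below it. None of the other comparisons was between tumours shown to share a lineage. The CV that such a pair would give is therefore unknown, and this test cannot exclude that explanation. A repeat deposit of the same library is argued against by the chi-square of 45.6 per degree of freedom. Whether any shared RNA came from the same tumour growing in another animal or from mixing during handling was not tested. The labels name no biological factor to set against these explanations.

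Malat1, a nuclear long noncoding RNA, held 0.489% of counts in lymphoma 4, 0.0440% in lymphoma 2, 0.0133% in lymphoma 3 and 0.00157% in lymphoma 1. In CPM + 1, its log2 ratio of lymphoma 1 to lymphoma 4 was -7.73. Longer transcripts were lower in lymphoma 1 relative to lymphoma 4 (Spearman rho -0.325 across 10934 genes, which are not independent replicates). After a fit on length, Malat1 still lay at -3.73 residual SDs, which argues against length bias as the whole cause. A loss of nuclear RNA from lymphoma 1 may contribute: 7 other nuclear noncoding RNAs had a median log2 ratio of -1.36, ranging from -4.57 for Neat1 to 0.54 for Firre. That median lies between the values set in advance for and against this explanation. Loss of nuclear RNA therefore cannot be told apart from a change in these RNAs themselves. Nor can it be told apart from length bias, since these ratios were not adjusted for length. Both tests address the low value in lymphoma 1. The high value in lymphoma 4 against lymphomas 2 and 3 was not tested. The design names no biological factor, and none was tested.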

How the results depend on the processing

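No paired analysis was possible because all samples form 1 group. The shares of receptor V segments gave no value under any setting, since no receptor segment was among the genes used here. With a pseudocount of 0.25 CPM, where log2 of a low value is negative, the mean levels of the erythroid (-0.249), stem and progenitor (-0.861), stroma (-0.761), pancreas (-1.79) and sex-linked (-0.404) lists fell below 0. With a threshold of 5 CPM, 9649.8 genes were detected per library on average. The 4-fold rule gave 4836 genes with a large spread and 1358 standing apart, more by construction. A pseudocount of 0.25 CPM gave 3572 genes with a large spread. In FPKM + 1, where values are smaller relative to the pseudocount, 918 genes had a large spread and 172 stood apart, and Trp63 averaged 0.179 FPKM, in a different unit from CPM. Leaving out 1 library at a time gave 1118 to 2175 genes with a large spread and 543 to 1093 standing apart. The lowest count of large spreads came without lymphoma 4, and the highest count standing apart without lymphoma 2. The mean Spearman rho between libraries was 0.708 with the filter of mean CPM of 5 or more, against 0.822 as reported. The mean rho between the 2 tables was 0.938 without a filter and 0.846 with the stricter filter, which narrow or widen the range of levels. The cause of the other shifts was not tested. Of 656 further values for named genes, lists and single libraries under the alternatives, 527 stayed within their limit and 129 moved by more. The limit was 1 SD between libraries for levels, 1.5 times for counts, 5 points for percentiles of spread and 1 SD over library pairs for a rho between libraries. DESeq2 size factors moved 2 of 90. The percentile of spread of a list often rested on 1 library. It left the 95th percentile without 1 library for the plasma cell, early B cell, pan T cell, CD4 and CD8, regulatory T cell, neutrophil, dendritic cell, stem and progenitor, proliferation and NF-kB lists. Other settings ended it for the plasma cell list (86.4 in FPKM), the dendritic cell list (93.45 with the stricter filter) and the stem and progenitor list (56.8 without a filter, 90.25 in FPKM, 93.5 with the stricter filter), and raised the erythroid (99.9 in FPKM), germinal centre (99.8 in FPKM), p63 target (96.3 with the pseudocount of 0.25 CPM) and oncogene lists (98.9 with the stricter filter) past it. At this depth a count of 0 allows up to 0.379 CPM, so genes below about 1 CPM, Trp73 among them, cannot be compared between libraries.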

Other observations

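The gene groups in the next paragraph were chosen after the data were seen. The tests on genes listed at 0 counts were fixed before their results.

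Ribosomal protein and glycolysis genes, for which no rank among random lists was computed, were mostly lowest in lymphoma 4. Of 81 ribosomal protein genes, 75 were highest in lymphoma 1 and 69 lowest in lymphoma 4, and their median log2(CPM + 1) was 11.6, 11.2, 10.7 and 10.04 in lymphomas 1 to 4. These transcripts are short, and across 10934 genes shorter transcripts were higher in lymphoma 1 relative to lymphoma 4 (Spearman rho with exonic length -0.325). Genes with symbols of Rpl or Rps followed by a digit held 19.99%, 16.8%, 13.5% and 10.5% of counts. That set differs from the 81 genes and leaves out Rpsa and Rplp0. Of 13 glycolysis genes, 9 were highest in lymphoma 1 and 9 lowest in lymphoma 4 (medians 8.56, 8.11, 8.68 and 6.40). Lymphoma 4 was also the library in which most proliferation genes were lowest. Genes of T cell receptor signalling had medians of 8.20, 7.96, 3.81 and 6.42, and 9 of 12 were lowest in lymphoma 3. Mki67, a marker of cycling cells chosen after its values were seen, was at 29.6, 58.4, 668 and 66.4 CPM, so it was low in lymphoma 1, where Pcna was highest. The Mki67 transcript is long, and longer transcripts were lower in lymphoma 1 relative to lymphomas 2, 3 and 4. Whether length accounts for this contrast was not tested.

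Among genes with FPKM of 10 or more in all libraries, 22 were listed at 0 counts in all of them. A candidate explanation is that reads matching a second copy of the sequence were left out of the counts. In the 20 of these genes with a transcript model, a median of 91.3% of 50-base words also occurred in transcripts of another gene, against a median of 0% in 200 other genes, and 17 of the 20 had over 50% shared. Eno1 was at 72.2%, but Rpl26 (47.4%), Oaz1 (20.1%) and Akr1b3 (0.643%) were lower, so the median does not speak for each gene. Several of the 20 are pseudogenes by their symbols, such as Rpl34-ps1 (100%) and Oaz1-ps (92.1%). A pseudogene resembles its parent gene by definition, so part of the contrast with the 200 other genes was fixed beforehand. Exons overlapping those of another gene were found for 25% of the 20, against 39.7% of 2453 other genes (one-sided Fisher's exact p = 0.946), which neither meets nor excludes what was set in advance for overlap as the cause. Levels of genes with near-identical copies, haemoglobin and some ribosomal protein genes included, are therefore uncertain in the counts.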
